A study of Mus musculus with 23 samples.

How the data were processed

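Per the labels, total RNA of mouse ES cells was measured on arrays for 4 lines and 3 plasmids (vector, the control SRFdM-VP16 and SRF-VP16), in 12 groups and 23 arrays. The deposited table holds 1 linear intensity per probe set and array. The software, background correction and scaling behind these intensities are not given in the sources used here. Of all values 29.1% were at or below 0, so a background or mismatch signal had been subtracted. Probe sets above 10000 had ratios of 0.923 to 1.05 to the median array, so bright values were on a common scale, while those from 300 to 600 had ratios of 0.598 to 1.37. The plan was to use values as deposited only if array medians were close or the authors had scaled them. Otherwise each array was to be divided by its median. Values were used as deposited because bright values were on a common scale, although medians were not close and no scaling is stated. This departs from the plan unless the authors had scaled the arrays. Division by the median and quantile normalization are given as alternatives. Array medians ran from 54 to 209 and the number of arrays limits the precision.

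Of 12502 probe sets, 66 control probe sets were left out of the comparisons. A probe set was kept if it lay above the 40th percentile of its array in at least 2 arrays, which kept 9643 and removed 2793. The planned floor, the 20th percentile of all values, was -43, and the lower floor also planned, the 10th percentile, was -133; a logarithm cannot take either. The higher floor planned beside them, the 40th percentile at 58, became the main one, and 39.9% of values lie below it. Values were then put on the log2 scale. Of the probe sets without controls, 10141 were paired with 1 gene symbol, 362 with several and 1933 with none. Of the symbols 10122 matched the reference gene table (assembly GRCm38.p6, used for names only), and 0 changed. The probe sets kept cover 6813 named genes. Names ending in _f_at mark probe sets that can hybridise to related transcripts.

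Comparisons used limma 3.58.1 in R 4.3.3, with 1 mean per group over all 23 arrays, moderated variances with an intensity trend, 11 residual degrees of freedom and Benjamini-Hochberg adjustment at 5%. All groups share 1 estimate of the spread, so a group left with 1 array is assumed to vary like the others. Tests were two-sided. The comparisons were SRF-VP16 against SRFdM-VP16 in the -/- lines, in wild type, in E99 and over all lines; SRFdM-VP16 against vector; -/- against wild type with vector and with SRFdM-VP16; E99 against wild type with vector; and the differences in the SRF-VP16 effect between -/- and wild type and between E81 and E100. Overlaps of calls were set against the number that independence gives.

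Gene lists covered actin cytoskeleton and SRF targets, immediate-early, striated-muscle, focal-adhesion, pluripotency, mesoderm, primitive-endoderm, neurectoderm, trophoblast, fibroblast, interferon-response, p53-target, apoptosis, cell-cycle, glycolysis and hypoxia, cholesterol-synthesis, heat-shock and ER-stress, and housekeeping genes. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation, under which 0 of the 8 list calls of the -/- comparison passed. Here camera compares a list with all other named genes, each by 1 probe set. Named genes were the 10 largest rises and falls past the threshold in each comparison (5 for the differences between lines) with 1 symbol and arrays that did not overlap between the groups in any line, up to 4 members of each list with the smallest adjusted p, and a fixed set of SRF targets and ES cell genes where measured. Where a gene had several probe sets, the one with the highest mean was used. Srf and Zyx were not analysed here. Groups, comparisons, lists, the naming rule and most alternatives were chosen before the data were examined.

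Alternatives were quantile normalization, division of each array by its median, no filter, a filter at the 60th percentile, a term for the replicate number within or across lines, no intensity trend, only the arrays of a comparison, vector as the control, each -/- line alone, and leaving out each array. A floor at the 60th percentile, an inverse hyperbolic sine in place of floor and logarithm, E100 alone for SRFdM-VP16 against vector, and leaving out the wild-type control arrays numbered 2 were chosen after seeing the data. The procedure was tested on simulated data with 50 changed probe sets per fold size among 9643. In the -/- comparison it recovered 40% of 2-fold, 78% of 4-fold and 92% of 8-fold changes, with 16 false of 170 calls. Over all lines it recovered 62% of 2-fold and 96% of 4-fold changes, with 16 false of 193 calls. In wild type it recovered 12% of 2-fold and 62% of 4-fold changes, with 9 false of 134 calls. In each of these comparisons the share of false calls was above the nominal false discovery rate. The real arrays differ in background, and some duplicates differ widely for the same genes. Whether the simulated rates hold for the real arrays was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.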

Results

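Total RNA from mouse embryonic stem (ES) cells was measured on 23 oligonucleotide arrays. SRF-VP16 joins serum response factor (SRF), a transcription factor of cytoskeletal, muscle and immediate-early genes, to the VP16 activation domain. Each of 4 lines, wild-type E14, E99 (+/-), E81 (-/-) and E100 (-/-), received an empty vector, the control plasmid SRFdM-VP16 or SRF-VP16, and RNA was taken 72 hours later. The labels do not name the gene behind +/- and -/-. There were 2 arrays in each of the 12 groups except the vector group of E100, which had 1. Array medians of intensity ran from 54 to 209, and 23.4% to 43.6% of the values of an array were at or below 0. The number of arrays limits the precision, and because nothing in the labels says whether duplicates were separate cultures, p-values measure only the spread between these samples. Values are log2 changes ± SE with limma's adjusted p, and intensities are mean ± SD. Intensities below a floor of 58 were set to 58 before the logarithm, so "at least" marks a change from or to a group with every array at the floor, and where some arrays were there its size depends on the floor.

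SRF-VP16 was compared with SRFdM-VP16 in the -/- lines, 4 arrays against 4, to ask which transcripts the SRF fusion changed where the locus carries no wild-type allele. The largest changes included a growth-factor binding protein, muscle actins and an early-response transcription factor. Igfbp6, which encodes a secreted binding protein of insulin-like growth factors, rose at least 323-fold (8.34 ± 0.38, adjusted p = 8.1e-08), from -176 ± 96.7 to 19280 ± 5535. Transgelin, an actin-binding protein of smooth muscle, rose 196-fold (Tagln, 7.61 ± 1.00, adjusted p = 0.00093), from 150 ± 59.2 to 27960 ± 4812. The smooth-muscle actin Acta2 rose at least 193-fold (7.60 ± 1.4, adjusted p = 0.0088), and the skeletal actin Acta1 at least 175-fold (7.45 ± 0.81, adjusted p = 0.00025). The zinc-finger factor Egr1 rose 69.2-fold (6.11 ± 0.49, adjusted p = 1.5e-05), from 243 ± 200 to 16160 ± 6308. Cytoplasmic gamma-actin was already abundant and rose 3.76-fold (Actg1, 1.91 ± 0.14, adjusted p = 7.2e-06), from 9182 ± 1410 to 34470 ± 4935. For each of these 6 genes all 4 SRF-VP16 arrays lay above all 4 SRFdM-VP16 arrays.

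Other large rises were in Nppb, which encodes a natriuretic peptide (6.11 ± 0.31), in F3, which encodes tissue factor (5.73 ± 0.86), and in the epithelial keratin Krt19 (5.69 ± 0.99, from a mean below the floor). Igf2, an embryonic growth factor, rose at least 178-fold by its brightest probe set (7.48 ± 1.21), while another Igf2 probe set read 0.00. Anxa1, a calcium-dependent membrane-binding protein, rose 97.7-fold by a probe set that can hybridise to related transcripts, and its other probe set gave 4.53. The falls were smaller. Klf2, a factor of the pluripotency network, fell 5.41-fold (-2.43 ± 0.35, adjusted p = 0.002), from 4138 ± 682 to 822 ± 369. Yipf4, a Golgi membrane protein, fell by 2.86 (SE 0.52), from 2088 ± 692 to 325 ± 312, and Gsta4, a glutathione transferase, fell by 1.19 (SE 0.20). The hair keratin Krt81 fell by at least 2.58, to the intensity floor. Zfp982 fell by 1.31 and Yju2 by 1.24, both by probe sets that can cross-hybridise. Nr5a2, an orphan nuclear receptor active at the Pou5f1 promoter, fell by 1.25, and its other probe set gave -0.86. Prkdc (-2.003), Zc2hc1c (-1.96) and Ntan1 (-1.51; another probe set -0.11) also fell. These last 3, Yju2 and Nr5a2 kept their calls in 10, 7, 11, 7 and 14 of 21 other settings, and all 5 lost them without E81 SRFdM-VP16 replicate 1, among other arrays.

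**Figure D1:**
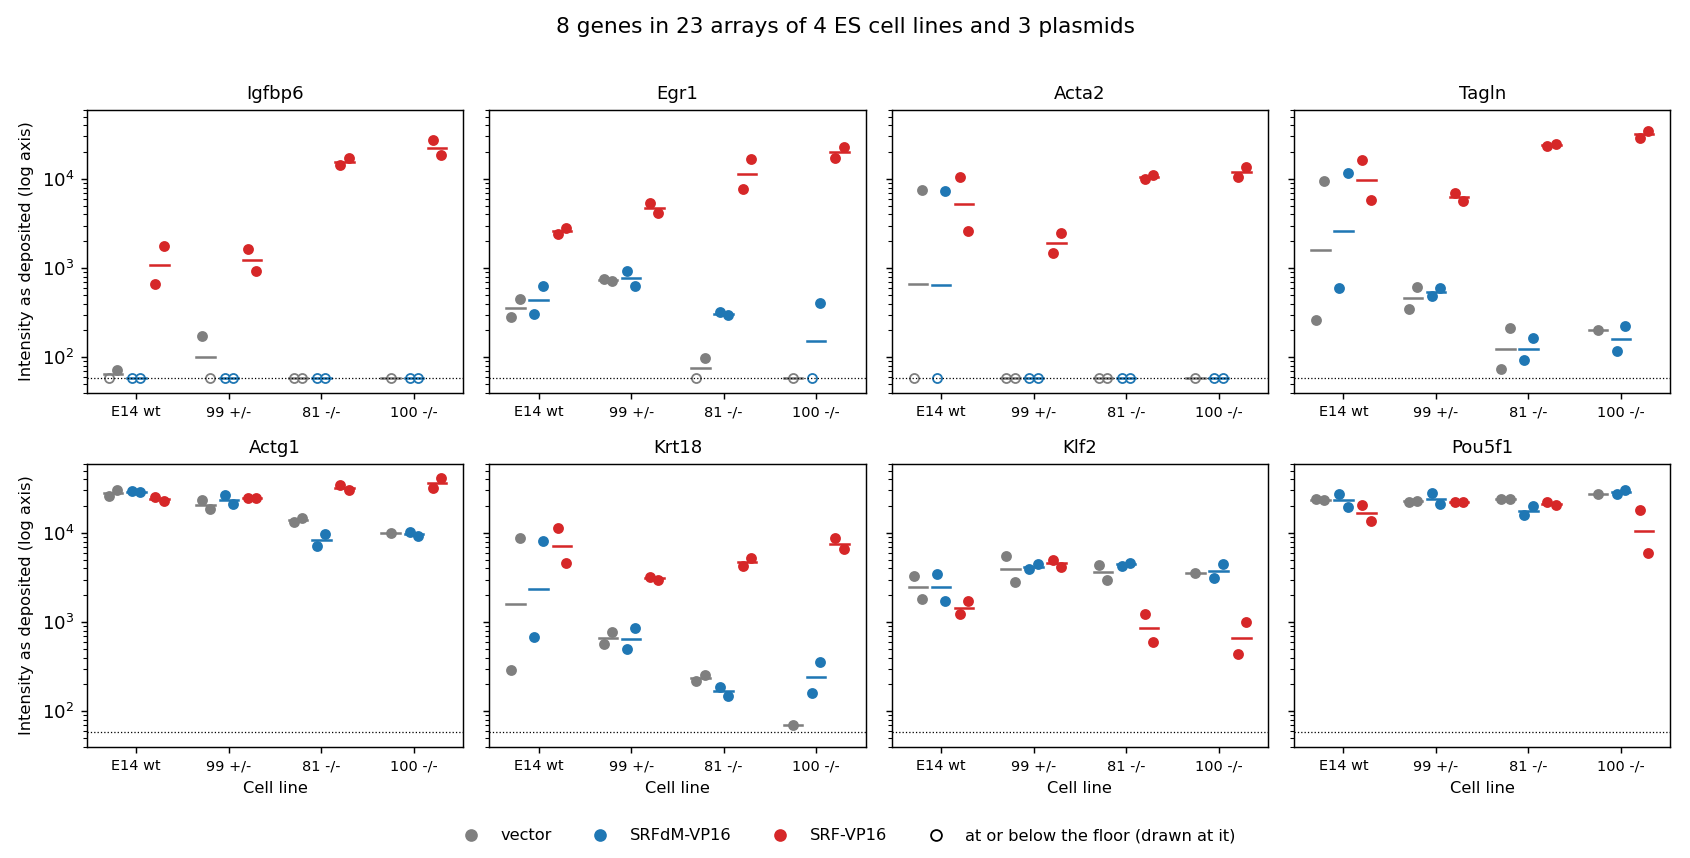
Intensity (log axis, arbitrary units) of 8 genes on each array, by line and plasmid, with a dash at each group's geometric mean, open points at or below the floor and a dotted line at the floor of 58. Igfbp6 stood at 14409 to 27179 on the 4 SRF-VP16 arrays of the -/- lines and at 659 to 1785 on those of wild-type cells.

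In all, 272 of 9643 probe sets passed a nominal 5% false discovery rate in the -/- lines, for 229 named genes. With SRF-VP16, 239 of them were higher and 33 lower. Of the 272 probe sets, 208 rose and 21 fell at least 2-fold. The share of higher calls depended on scaling, with 238 higher and 109 lower after quantile normalization and 165 higher and 119 lower after division of each array by its median, which moved the median of all probe sets from 0.04 to -0.16. With vector in place of SRFdM-VP16 as the control the calls were 150 higher and 136 lower. E81 SRFdM-VP16 replicate 1 stood apart: it had the lowest Gapdh 5 prime over 3 prime ratio (-0.93), the lowest median correlation with the other arrays (0.878) and the most values at or below 0 (43.6%), which can mark poor RNA or a poor array. Without it the count was 214, 171 higher and 43 lower. Without replicate 2, which leaves that array alone in its group, it was 514. The count was 112 in a fit of the 8 arrays alone, 97 in E81 alone and 114 in E100 alone.

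Gene lists fixed in advance were then tested. None that passed at the preset correlation passed with an estimated one. Of 31 measured genes of the actin cytoskeleton and other SRF targets, 16 rose and none fell over all genes tested (18 adjusted over the list alone), with a median of 1.48 and a list test of adjusted p = 4.8e-17 (0.066 with an estimated correlation). Besides the actins, vinculin, which anchors actin at adhesions, rose 15.2-fold (Vcl, 3.92 ± 0.60; another probe set 1.74), and Fhl2, a LIM-domain cofactor, rose 10.3-fold (3.36 ± 0.47). Actc1 (3.71 ± 0.36) and Actg2 (1.51 ± 0.29) rose by probe sets that can cross-hybridise between actins, and the Actg2 call was lost after division by the array median. Beta-actin did not pass (Actb, 0.76 ± 0.36, adjusted p = 0.40), nor did calponin (Cnn1, 2.81 ± 0.82, adjusted p = 0.10) or Fhl1 (0.52, adjusted p = 0.66). Cnn1 passed in 3 of 21 other settings. Control probe sets for the 5 prime, middle and 3 prime parts of beta-actin were 2.82, 2.09 and 0.30 higher with SRF-VP16 (exact permutation p = 0.0286, 0.0286 and 0.457). Of 21 immediate-early genes, 4 rose (11 adjusted over the list alone), with a median of 1.27 and a list test of adjusted p = 2.8e-06 (0.071 with an estimated correlation). They were Egr1, Egr2 (13.03-fold, 3.70 ± 0.27), the matricellular Ccn1 (4.54 ± 0.78) and Jun (2.81 ± 0.58), the last 2 from means below the floor (45.8 ± 78.2 for Ccn1), while Fos did not change detectably (-0.12, adjusted p = 0.95). Of 22 striated-muscle genes, 4 rose, also 4 adjusted over the list alone (adjusted p = 0.0061; 0.071 with an estimated correlation). They were Nppb, slow troponin C (Tnnc1, at least 17.1-fold, 4.10 ± 0.38), the calcium pump Atp2a1 (1.47 ± 0.24) and alpha-actinin 3 (Actn3, 1.71 ± 0.38; another probe set 0.63). Actn3 lost its call under both other scalings, Jun and Actn3 when any 1 of 4 arrays was left out (13 and 10 of 21 other settings kept them), and Actg2 without E100 SRFdM-VP16 replicate 2.

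Among 20 focal-adhesion genes, 4 rose, also 4 adjusted over the list alone (adjusted p = 0.00011; 0.15 with an estimated correlation). These were Vcl, alpha-actinin 1 (Actn1, 1.48 ± 0.26), the integrin-linked kinase Ilk (1.59 ± 0.33) and integrin beta 1 (Itgb1, 0.87 ± 0.19). Actn1 and Itgb1 lost their calls after division by the array median. Pluripotency genes moved the other way: of 27, 2 fell (8 adjusted over the list alone), with a median of -0.61 and a list test of adjusted p = 8.1e-11 (0.071 with an estimated correlation). The 2 were Klf2 and Fgf4, a growth factor secreted by ES cells, which fell by 1.15 (SE 0.22), from 9279 ± 2286 to 4273 ± 1406. Changes in this list, and in the cell-cycle list that follows, were higher in E81 than in E100 (compared below). The falls of both lists thus lay more in E100. The 33 probe sets called lower in this comparison had medians of -0.70 in E81 and -1.57 in E100. Pou5f1, the central ES cell factor, did not pass (-0.60 ± 0.27, adjusted p = 0.34), except without E100 SRF-VP16 replicate 1. Of 28 cell-cycle genes only the proliferation marker Mki67 fell, by 0.95 (SE 0.20; 2 adjusted over the list alone), and the list went down (adjusted p = 7.4e-05; 0.35 with an estimated correlation). Of 9 trophoblast genes, 2 rose, also 2 adjusted over the list alone: Krt7 at least 19.8-fold (4.30 ± 0.41) and Tpbpa, which stayed near the floor (0.85 ± 0.11). The Tpbpa value is no lower bound, because some SRF-VP16 arrays were at the floor too, and its effect differed by -1.71 in E81 against E100. That list went up (adjusted p = 0.0018; 0.14 with an estimated correlation). Of 21 primitive-endoderm genes, 4 rose (5 adjusted over the list alone), namely Krt8 (12.2-fold, 3.61 ± 0.57), Krt18 (30.1-fold, 4.91 ± 0.89), Col4a1 (6.41-fold, 2.68 ± 0.55) and Col4a2 (1.86 ± 0.45). The list test gave adjusted p = 0.022 (0.35 with an estimated correlation), and Col4a2 kept its call in 5 of 21 other settings. Single arrays ended the calls of Fgf4 (E100 SRFdM-VP16 replicate 2) and, among several that did, of Ilk, Itgb1, Mki67 and Col4a1 (E100 SRFdM-VP16 replicate 2 for the first 3, E81 SRFdM-VP16 replicate 1 for Col4a1), which kept them in 12, 13, 13 and 14 of 21 settings.

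The remaining lists did not pass. The interferon-response list (15 measured, adjusted p = 0.26) held 1 rise, the ubiquitin-like Isg15 (at least 47.2-fold, 5.56 ± 0.59). The heat-shock and ER-stress list (16 measured, adjusted p = 0.54) held the chaperone Hspa5 (1.15 ± 0.26), whose call was lost after division by the array median, and the neurectoderm list (12 measured, adjusted p = 0.88) held the intermediate filament Nes (2.94 ± 0.53). Glycolysis and hypoxia genes (20 measured, adjusted p = 0.074) and p53 targets (9 measured, adjusted p = 0.18) had 0 calls over all genes tested and 3 and 2 adjusted over the list alone. Mesoderm genes (13 measured, adjusted p = 0.88), fibroblast genes (15 measured), apoptosis regulators (18 measured) and housekeeping controls (11 measured; each adjusted p = 0.83), and cholesterol-synthesis genes (15 measured, adjusted p = 0.79) had 0 by limma's test. The 1294 probe sets of this comparison at an unadjusted p under 0.05 are the wider background to these counts of 0.

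**Figure D2:**
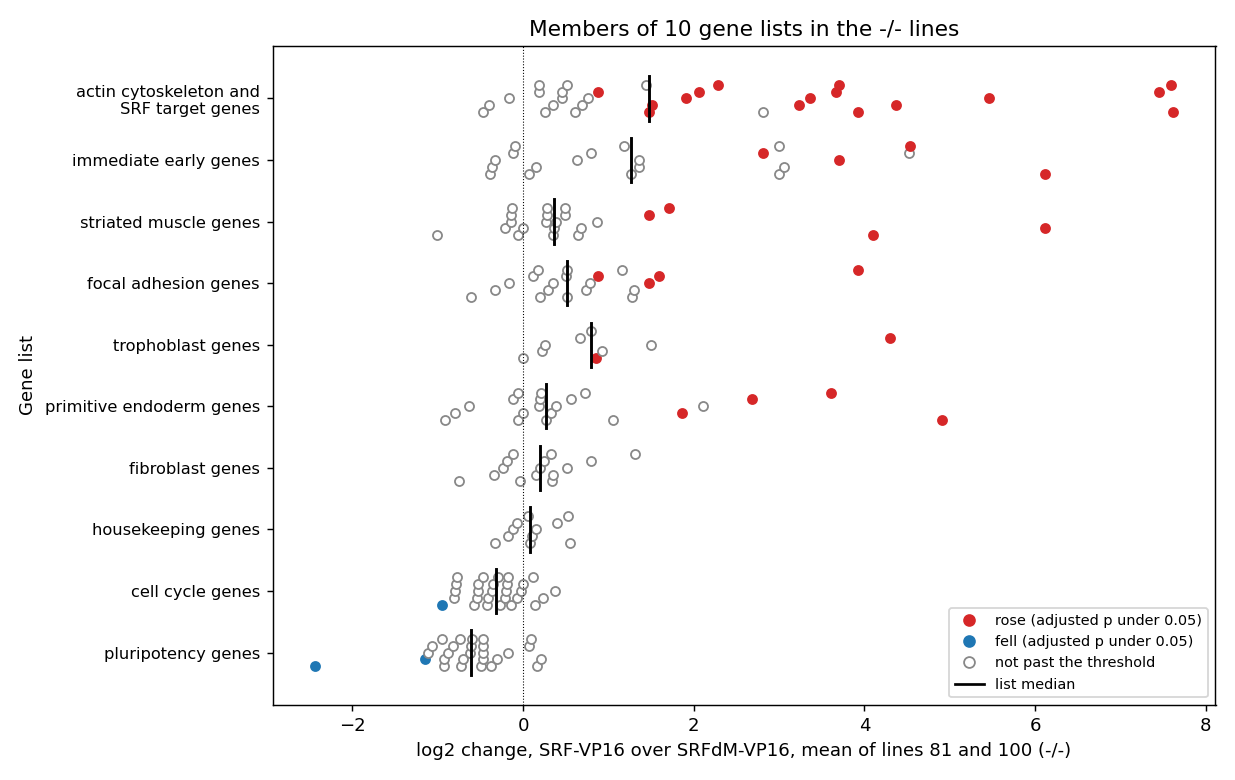
Log2 change of each measured member of 10 lists, SRF-VP16 against SRFdM-VP16 in the -/- lines; red points rose and blue points fell past the threshold, open points did not pass, and the bar is the list's median. The medians were 1.48 for the actin and SRF-target list and -0.61 for the pluripotency list.

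The same comparison in wild-type E14 cells, 2 arrays against 2, asked what the fusion changed beside intact alleles. Igfbp6 rose here too, at least 18.7-fold (4.23 ± 0.54, adjusted p = 0.012), from -16.5 ± 79.9 to 1222 ± 796. It was the only named gene of 2 probe sets that passed, with 346 at an unadjusted p under 0.05. Egr1 stood at 2621 ± 276 against 464 ± 227, a change of 2.59 ± 0.69 that did not pass (adjusted p = 0.94). Acta1 (3.91 ± 1.15), Acta2 (3.004 ± 1.98) and Tagln (1.88 ± 1.41) had large spreads and did not pass. Wild-type SRFdM-VP16 replicate 2 read 7302 for Acta2 and 11738 for Tagln, against -52 and 591 in replicate 1, and the vector arrays split alike. Without both wild-type control arrays numbered 2, Acta1 read 5.97, Acta2 6.49 and Tagln 4.04. Those arrays were singled out because such genes were high in them, so leaving them out raises these changes by construction. It also leaves only replicate 1 of SRFdM-VP16. Acta1 and Acta2 passed in no setting that kept either array. The actin and SRF-target list did not pass (adjusted p = 0.44). Without those arrays the list medians were 0.84 for actin and SRF targets, -0.50 for pluripotency, -0.28 for cell-cycle and 1.06 for interferon-response genes. Without replicate 1 of wild-type SRFdM-VP16, Acta2 read -0.48 and Tagln -0.27. Actg1 (-0.26) and Pou5f1 (-0.47) did not pass. Pluripotency genes went down as a list (adjusted p = 0.015; 0.85 with an estimated correlation) with 0 members called over all genes or over the list alone. Trophoblast genes went up (adjusted p = 0.015; 0.42 with an estimated correlation), with 0 members called over all genes and 2 adjusted over the list alone. Igfbp6 kept its call in 10 of 16 other settings and lost it without wild-type SRFdM-VP16 replicate 2, and the count was 7 under quantile normalization or division by the median, 12 with vector as the control and 0 in a fit of these arrays alone. The direction of the calls depended on single arrays. Nearly all were lower without replicate 1 of wild-type SRFdM-VP16 and nearly all higher without replicate 2 of wild-type SRF-VP16. Each of these fits leaves its group without a duplicate. Leaving out either E100 SRF-VP16 array gave 5 calls.

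In E99 (+/-), 2 arrays against 2, Igfbp6 rose at least 21.2-fold (4.41 ± 0.54, adjusted p = 0.0077), from -196 ± 99.0 to 1278 ± 484. Ppfibp2, a liprin scaffold, rose by at least 1.27, and Gramd3 and the melanocortin receptor Mc3r fell by at least 1.79 and 1.64, all near the floor. These 4 were all the calls, with 432 probe sets at an unadjusted p under 0.05. Egr1 stood at 4775 ± 815 against 779 ± 208 (2.63 ± 0.69, adjusted p = 0.51), and Acta2 (5.05), Tagln (3.53), Acta1 (3.66) and Fhl2 (2.08) did not pass. The actin and SRF-target list went up (adjusted p = 0.0029; 0.91 with an estimated correlation) with 0 members called over all genes or over the list alone. Immediate-early genes went up too (adjusted p = 0.039; 0.91 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. Both E99 SRFdM-VP16 arrays had over 34% of values at or below 0 (34.0% and 38.3%), and both SRF-VP16 arrays had under 26% (25.2% and 25.6%), so background and plasmid cannot be told apart for the dim calls of this line. Igfbp6 kept its call in 10 of 15 other settings; it and Mc3r lost theirs without SRFdM-VP16 replicate 2. The count was 9 without a filter or without a floor, 10 with vector as the control and 0 in a fit of these arrays alone; it was 7 without either vector array, 9 without SRFdM-VP16 replicate 1, and 13 and 23 without SRF-VP16 replicates 1 and 2 of this line.

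Averaged over the 4 lines, 8 arrays against 8, SRF-VP16 raised Igfbp6 (at least 6.33 ± 0.27, adjusted p = 3.2e-08), Acta2 (5.81 ± 0.99, adjusted p = 0.0081), Acta1 (5.62 ± 0.57, adjusted p = 2e-04), Tagln (5.16 ± 0.70, adjusted p = 0.0017), Egr1 (4.36 ± 0.35, adjusted p = 2.6e-05) and Nppb (4.31 ± 0.22, adjusted p = 1.2e-07). Igf2 (6.13), F3 (4.10), Krt19 (4.30) and the annexin Anxa2 (3.59 ± 0.57) were among the other large rises, and Klf2 fell by 1.38 (SE 0.25). Cnn1 passed here (2.52, adjusted p = 0.042) and kept its call in 13 of 28 other settings. Actg1 rose by 0.91, Vcl by 2.18, Fhl2 by 2.62 and Isg15 by 3.35, whereas Actb (0.12), Fos (0.35), Fhl1 (0.44), Actg2 (0.74) and Pou5f1 (-0.45) did not pass. The Isg15 mean includes a change of 0 in E99, so it is no lower bound. Irf1, an interferon-response factor, rose by 0.92 (adjusted p = 0.044) and read -0.09 with vector as the control. Jun (1.76), Atp2a1 (0.74) and Irf1 kept their calls in 12 of 28, 10 of 27 and 9 of 28 other settings, and Vcl lost its call without wild-type SRF-VP16 replicate 1; Pou5f1 passed without E100 SRF-VP16 replicate 1 and Actg2 without wild-type SRF-VP16 replicate 2. Of the actin and SRF-target genes 16 rose (18 adjusted over the list alone; adjusted p = 2.1e-14, 0.081 with an estimated correlation). Of the immediate-early genes 4 rose (9 adjusted over the list alone; adjusted p = 5.4e-06, 0.081 with an estimated correlation), and 1 pluripotency gene fell (6 adjusted over the list alone; adjusted p = 1.2e-10, 0.081 with an estimated correlation). There were 189 calls, 173 higher and 16 lower, for 163 named genes. The split was 168 higher and 73 lower under quantile normalization and 124 higher and 218 lower after division by the median, where the median of all probe sets was -0.17 in place of 0.08, so the preponderance of rises depends on scaling. Leaving out 1 array gave 108 calls without E99 SRF-VP16 replicate 1, 109 without wild-type SRF-VP16 replicate 1, 286 without E100 SRF-VP16 replicate 2 and 432 without E81 SRFdM-VP16 replicate 2.

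Whether the response differed between -/- and wild-type lines was tested directly. E14 is the only wild-type line, so genotype and line cannot be told apart here either. The effect of SRF-VP16 was larger in the -/- lines for Egr2 (5.32 ± 0.47, adjusted p = 0.00014), the retinoid-binding Crabp2 (4.31 ± 0.56, adjusted p = 0.0069), Igfbp6 (4.11 ± 0.67, adjusted p = 0.041), Tnnc1 (4.003 ± 0.66, adjusted p = 0.042), Nppb (3.31 ± 0.53, adjusted p = 0.041) and Actg1 (2.17 ± 0.25, adjusted p = 0.0019). Actg1 did not pass in wild-type cells, where it was 28860 ± 544 with SRFdM-VP16 and 24080 ± 1497 with SRF-VP16. For Tagln (5.73, adjusted p = 0.53), Egr1 (3.53, adjusted p = 0.28), Acta2 (4.59, adjusted p = 0.97) and Vcl (3.39, adjusted p = 0.54) a difference between the lines was not shown. For Igfbp6 and Tnnc1 every SRFdM-VP16 array on both sides was at the floor, so these values set the SRF-VP16 arrays against each other and are not exact differences in effect. There were 8 calls, all higher in the -/- lines, the other named one being Scrg1, near the floor. That direction turned without E81 SRFdM-VP16 replicate 2 (12 higher, 16 lower) and without wild-type SRF-VP16 replicate 2 (9 higher, 12 lower). As a list, actin and SRF-target genes responded more in the -/- lines (adjusted p = 9.9e-14; 0.13 with an estimated correlation), with 1 member called over all genes and 9 adjusted over the list alone. So did immediate-early genes (adjusted p = 0.00031; 0.35 with an estimated correlation; 1 member called over all genes and 2 over the list alone) and focal-adhesion genes (adjusted p = 0.00079; 0.38 with an estimated correlation). The difference was negative for pluripotency genes (median -0.50, adjusted p = 0.00079, and 0.43 with an estimated correlation). It was negative too for cell-cycle genes (median -0.34, adjusted p = 0.0043, and 0.69 with an estimated correlation). The cell-cycle median in wild type was 0.05, and -0.28 without the wild-type control arrays numbered 2. These last 3 lists held 0 calls by limma over all genes or over the list alone. The difference in the actin list depends in part on wild-type SRFdM-VP16 replicate 2, with its 7302 for Acta2 and 1007 for Acta1 against -52 and 49 in replicate 1. Without the wild-type control arrays numbered 2 its median went from 1.34 to 0.93 (adjusted p = 2.1e-07; 0.39 with an estimated correlation), and the pluripotency and cell-cycle lists did not pass (adjusted p = 0.23 and 0.83). Of the 239 probe sets higher in the -/- lines, 168 (70.3%) were above 0 in wild-type cells and 182 (76.2%) in E99, against 53.4% and 59.9% of all probe sets. Across genes, which are not independent, changes in the -/- lines correlated with those in wild-type cells at r = 0.24 and rho = 0.18. Igfbp6 and Tnnc1 kept their difference in 8 of 23 other settings each and Nppb in 13, and these 3 and Crabp2 lost it without wild-type SRFdM-VP16 replicate 2. Leaving out 1 array gave counts from 4 (without E99 SRFdM-VP16 replicate 1) to 41 (without E100 SRF-VP16 replicate 2); it was 28 and 5 without wild-type SRFdM-VP16 replicates 1 and 2, 5 without E99 SRFdM-VP16 replicate 2, 13 and 28 without E81 SRFdM-VP16 replicates 1 and 2, 5 and 13 without those of E100, 21 without wild-type SRF-VP16 replicate 2, 5 without either E99 SRF-VP16 array and 29 without E100 SRF-VP16 replicate 1.

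E81 and E100, the pair of -/- lines, were compared to ask whether they responded alike. The main muscle and actin genes did not differ detectably: Tagln 0.01, Acta2 -0.19 and Actg1 0.06 (adjusted p = 0.98). The 14 calls, 5 higher and 9 lower in E81, a split that turned when single arrays were left out, were for dim genes, among them Scrg1 (2.06 ± 0.24, adjusted p = 0.0033), Slc1a1 (1.30), Alas2 (0.90) and the chemokine Ccl12 (0.77). Those lower were Rragd (-2.44 ± 0.43, adjusted p = 0.047), the homeobox gene Meis3 (-2.15 ± 0.24, adjusted p = 0.0033), the trophoblast gene Tpbpa (-1.71), Pag1 (-1.68) and the homeobox gene Dlx3 (-1.34). The list tests compare a list with all other named genes, each by 1 probe set. Over all probe sets, named or not, the median difference was 0.52. Against the other named genes, trophoblast genes were lower in E81 (median -0.44, adjusted p = 9.4e-05, and 0.17 with an estimated correlation). So were interferon-response genes (median -0.28, adjusted p = 0.035, and 0.64 with an estimated correlation). The actin and SRF-target list also tested lower (adjusted p = 0.032; 0.73 with an estimated correlation), but its own median was 0.06. Cell-cycle (median 1.11, adjusted p = 0.00035) and pluripotency genes (median 1.06, adjusted p = 0.0079; both 0.64 with an estimated correlation) were higher. Tpbpa was called over all genes and in its list alone, and these 5 lists held no other call by either count. All 4 E81 arrays compared had 34.2% to 43.6% of values at or below 0 and no E100 array over 26.5%, so line and background cannot be told apart for these dim calls. Rragd and Pag1 kept their calls in 3 and 4 of 17 other settings. The count was 0 with the filter at the 60th percentile and 22 without a filter; without 1 array it was 7 (either E99 SRFdM-VP16 array), 430 (E81 SRFdM-VP16 replicate 2; 354 higher and 76 lower), 34 (E81 SRF-VP16 replicate 2; 23 and 11), 28 (E100 SRFdM-VP16 replicate 2, with 21 and 7), 104 and 56 (E100 SRF-VP16 replicates 1 and 2, with 60 and 44, and 8 and 48). It was also 12 higher and 5 lower without E100 SRFdM-VP16 replicate 1, and 10 and 5 without E81 SRF-VP16 replicate 1.

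The lines were then compared without SRF-VP16. E14 is the only wild-type line, so genotype and line cannot be told apart in these comparisons. With vector, 3 -/- arrays against 2 wild-type arrays, gamma-actin was 2.34-fold lower in the -/- lines (Actg1, -1.22 ± 0.19, adjusted p = 0.011), at 12750 ± 2425 against 27900 ± 3086. The Y-linked translation factor Eif2s3y was lower, by a probe set that can cross-hybridise (-3.97 ± 0.49, adjusted p = 0.0032). Csrp3, a muscle LIM protein, was lower by at least 2.13, and Slc6a18 (-3.32), Ltbp2 (-2.002), Oprk1 (-1.12), Cmbl (-1.06), Kif9 (-1.05) and Rcbtb1 (-0.86) were also lower, while Gfra1 (0.75), Npas1 (0.69), Rab5b (0.58) and Pde9a (0.49) were higher. All -/- arrays were at the floor for these lower genes and Eif2s3y (for Oprk1 only some), as were both wild-type arrays for Npas1, Rab5b and Pde9a, so those differences are lower bounds. Egr1 (-2.43 ± 0.65, adjusted p = 0.30), Tagln (-3.32, adjusted p = 0.96) and Acta2 (-3.50) did not pass. The actin and SRF-target list was lower in the -/- lines (adjusted p = 6.1e-12; 0.20 with an estimated correlation), with 1 member called over all genes and 1 adjusted over the list alone. Wild-type vector replicate 2 read 7463 for Acta2, 9417 for Tagln and 2294 for Csrp1 against -242, 264 and 274 in replicate 1. Without the wild-type control arrays numbered 2 the list's median went from -0.62 to -0.22 (adjusted p = 0.013; 0.99 with an estimated correlation), and the next 2 lists did not pass (adjusted p = 0.98 and 0.95). Immediate-early genes were lower (adjusted p = 0.039) and cholesterol-synthesis genes higher (adjusted p = 0.04; both 0.92 with an estimated correlation), with 0 members called over all genes and 1 and 0 adjusted over the list alone. Actg1 kept its call in 10 of 17 other settings and lost it after division by the array median and without wild-type vector replicate 2. There were 22 calls, 12 higher and 10 lower, and 459 probe sets at an unadjusted p under 0.05. The count was 3 under quantile normalization, 1 after division by the median, 2 with the filter at the 60th percentile and 87 without a filter. It was 132 in a fit of these arrays alone, 0 without a floor, 61 and 46 without wild-type vector replicates 1 and 2, 34 without E99 vector replicate 2, 43 and 42 without E81 vector replicates 1 and 2, and 35 without either E100 SRFdM-VP16 array. The direction depended on single arrays: 13 higher and 48 lower, and 8 and 38, without wild-type vector replicates 1 and 2, but 31 and 12, and 29 and 13, without those of E81.

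With SRFdM-VP16, 4 -/- arrays against 2, gamma-actin was again lower, 3.17-fold (Actg1, -1.67 ± 0.17, adjusted p = 0.0011), at 9182 ± 1410 against 28860 ± 544. Eif2s3y (-3.20 ± 0.46, adjusted p = 0.025) and Cd7 (by at least 1.41, adjusted p = 0.027) were also lower, and these 3 genes and 1 unnamed probe set were all the calls, with 421 at an unadjusted p under 0.05. The actin and SRF-target list was lower (adjusted p = 1.9e-17; 0.061 with an estimated correlation), with 1 member called over all genes and 7 adjusted over the list alone. Focal-adhesion genes were lower too (adjusted p = 0.029; 0.77 with an estimated correlation), with 0 called over all genes or over the list alone. Wild-type SRFdM-VP16 replicate 2 read 7302 for Acta2, 11738 for Tagln and 2258 for Csrp1, against -52, 591 and 252 in replicate 1. Without the wild-type control arrays numbered 2 the actin list's median went from -0.55 to -0.21 (adjusted p = 0.00048; 0.82 with an estimated correlation), with Actg1 the only member called by either count, and the focal-adhesion list did not pass (adjusted p = 0.12). Eif2s3y and Actg1 were lower under both plasmids. The same lines were compared each time, so any difference between lines would recur. The 0.00415 shared calls that independence gives are therefore no measure of this overlap. Eif2s3y was also lower in E99 than in wild type. Actg1 kept its call in 17 of 19 other settings and lost it after division by the array median, and Eif2s3y lost its call without wild-type SRFdM-VP16 replicate 2. Without 1 array the count was 43 (wild-type SRFdM-VP16 replicate 1), 10 and 48 (E81 SRFdM-VP16 replicates 1 and 2, with 6 and 38 higher), 16 (E100 SRFdM-VP16 replicate 2, with 11 higher) and 2 (either E99 SRFdM-VP16 array, either E81 SRF-VP16 array or E99 SRF-VP16 replicate 1).

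Of the 10 probe sets lower in the -/- lines with vector, 2 were among the 239 that rose with SRF-VP16, where independence gives 0.248: Actg1 and Nr4a2, an orphan nuclear receptor of the immediate-early class. Meis3 was higher in both comparisons. Across genes, which are not independent, the changes correlated at r = -0.27 and rho = -0.19. These comparisons share no array, and the overlap was 1 under quantile normalization. The wild-type arm holds wild-type vector replicate 2, which read high for genes of this response (7463 for Acta2 and 9417 for Tagln). Such values make these genes look lower in the -/- lines. The correlation was not computed without that array, and Actg1 lost its call without it.

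E99 was compared with wild-type cells under vector, 2 arrays against 2; the wild-type arrays are those of the -/- comparison, so shared calls are not independent. Nmt2, an N-myristoyltransferase (1.65, adjusted p = 0.0027), Cd7 (by at least 1.73, adjusted p = 0.0094) and Vmn2r30 (0.83) were higher in E99. Eif2s3y (-3.74, adjusted p = 0.0094), Slc6a18 (-3.32), Csrp3 (-2.13), Ltbp2 (-2.002), Igll1 (-1.84), Oprk1 (-1.36), Kcnj1 (-1.25), Kif9 (-1.05) and Rcbtb1 (-0.74) were lower, and Actg1 did not pass (-0.42, adjusted p = 0.95). Both E99 arrays were at the floor for Slc6a18, Csrp3, Ltbp2, Igll1, Oprk1, Kcnj1 and Kif9, so these are lower bounds, and 4 of them repeat the values of the -/- comparison because the wild-type arrays and the floor are the same. The actin and SRF-target list was lower in E99 (adjusted p = 0.0032), with 0 members called over all genes and 1 adjusted over the list alone. Focal-adhesion (adjusted p = 0.039) and p53-target genes (adjusted p = 0.025) were lower and pluripotency genes, with a median of 0.01 against -0.15 for all probe sets, tested higher (adjusted p = 0.038), with 0 members called over all genes and 1, 0 and 0 adjusted over the list alone; all 4 list tests gave 0.75 with an estimated correlation. Wild-type vector replicate 2 read 7463 for Acta2 and 9417 for Tagln against -242 and 264 in replicate 1, and without the wild-type control arrays numbered 2 none of the 4 passed (each adjusted p = 0.92). Ltbp2, Kif9 and Kcnj1 kept their calls in 2, 2 and 0 of 14 other settings. There were 16 calls, 6 higher and 10 lower. The count was 3 under quantile normalization, 2 after division by the median, 0 with the filter at the 60th percentile, without a floor or in a fit of these arrays alone, and 48 without wild-type control arrays numbered 2. Without 1 array it was 39 and 49 (wild-type vector replicates 1 and 2), 43 and 50 (E99 vector replicates 1 and 2) and 10 (either E99 SRFdM-VP16 array). The direction depended on them: 7 higher and 32 lower, and 7 and 42, without the wild-type arrays, against 35 and 8, and 44 and 6, without those of E99 with vector, and 6 and 4 without either with SRFdM-VP16.

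The control plasmid SRFdM-VP16 was set against vector over the 4 lines, 8 arrays against 7, to see what it changed without the intact fusion. Gfi1, a zinc-finger repressor, rose by 1.87 (SE 0.34, adjusted p = 0.025), from -19.0 ± 85.9 to 284 ± 204. The elastase gene Cela1 fell by 2.01 (SE 0.36, adjusted p = 0.025), from 423 ± 89.9 to 50.4 ± 171, and the neurogenic factor Neurog1 by 1.73 (SE 0.28, adjusted p = 0.02). Other falls were in Znrf4 (-1.59), Meig1 (-1.58), Igkv4-59 (-1.57), Smc6 (-1.51), Meg3 (-1.45; another probe set -0.20), Tctex1d4 (-1.38), the myelin gene Mobp (-1.38) and Ccr1l1 (-1.33). The SRF targets Egr1 (0.95, adjusted p = 0.26), Fhl2 (-1.08, adjusted p = 0.17) and Actg1 (-0.14, adjusted p = 0.60) did not pass, and no list did (smallest adjusted p = 0.073, neurectoderm). Of 77 calls 3 were higher and 74 lower; the lower ones were dim, with a median intensity of 56.0, and the median of all probe sets was -0.20. Of the 8 SRFdM-VP16 arrays 5 had 34.0% to 43.6% of values at or below 0, against 25.2% to 26.95% on the 7 vector arrays. The count was 1 under quantile normalization and under division by the median. It was 0 with the filter at the 60th percentile, 179 without a filter and 120 without a floor. With a block for the replicate number within lines it was 2, and every gene named here as changed lost its call. Differences between replicates 2 and 1 correlated between the vector and SRFdM-VP16 groups of the same line, at 0.42 in wild type, 0.32 in E99 and 0.31 in E81. Between lines, wild-type vector gave 0.29 with E100 SRFdM-VP16 and -0.28 with E99 SRFdM-VP16. The same-line values therefore do not show that the numbers pair arrays within a line. Without 1 array it was 49 and 116 (wild-type SRFdM-VP16 replicates 1 and 2), 4 (E99 SRFdM-VP16 replicate 2, without which Gfi1, Cela1 and Neurog1 lost their calls), 48 and 372 (E81 SRFdM-VP16 replicates 1 and 2) and 33 (E100 SRFdM-VP16 replicate 2).

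**Figure D3:**
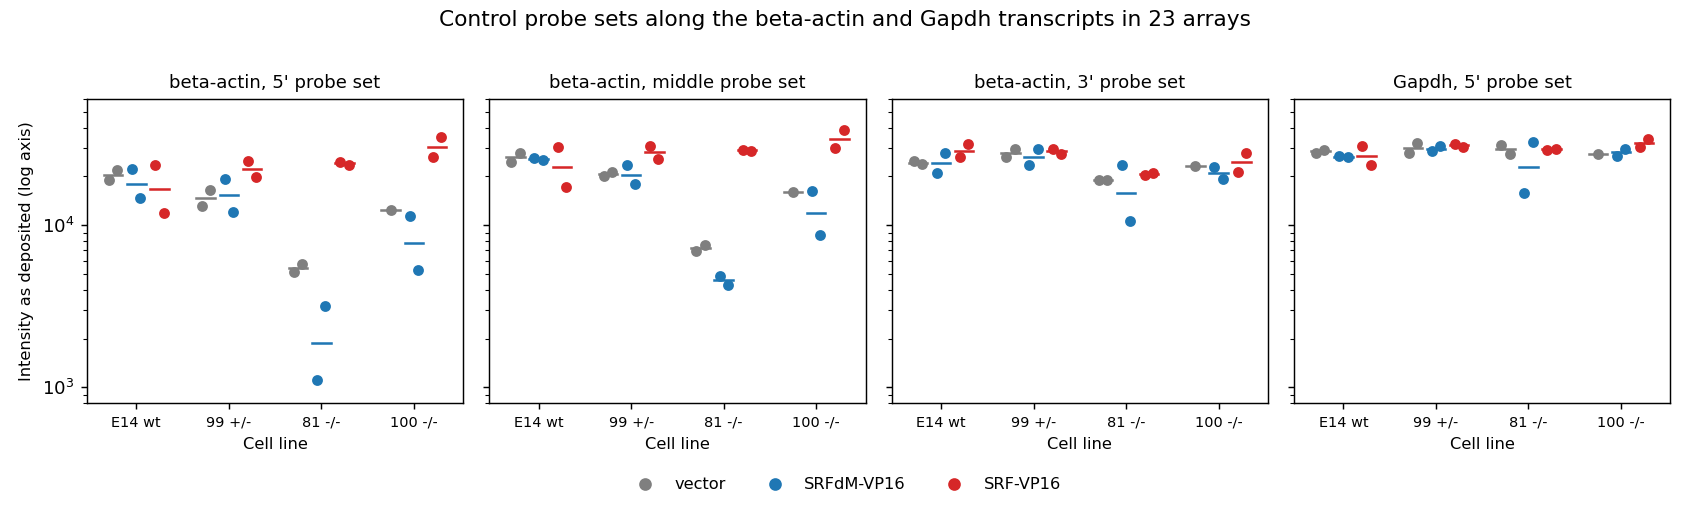
Intensity (arbitrary units) of the control probe sets for the 5 prime, middle and 3 prime parts of beta-actin and the 5 prime part of Gapdh on each array, by line and plasmid. Beta-actin 5 prime averaged 6346 on the 7 vector and SRFdM-VP16 arrays of the -/- lines and 27380 on their 4 SRF-VP16 arrays, while Gapdh 5 prime averaged 27310 and 30720.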

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

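The tests of mislabelled arrays, fibroblast RNA, RNA degradation and array scaling below were chosen after the results were seen; the comparisons with other splits of the arrays were planned.

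Differences between groups in the effect of SRF-VP16 were called by direct tests. Between the -/- and wild-type lines 8 probe sets passed, with larger effects in the -/- lines for Egr2 (5.32), Crabp2 (4.31), Igfbp6 (4.11), Tnnc1 (4.003), Nppb (3.31) and Actg1 (2.17). For Igfbp6 and Tnnc1 all SRFdM-VP16 arrays of the -/- and wild-type lines were at the floor, so those values are not exact. Between E81 and E100 14 passed: Scrg1 (2.06), Slc1a1 (1.30), Alas2 (0.90) and Ccl12 (0.77) were higher in E81, and Rragd (-2.44), Meis3 (-2.15), Tpbpa (-1.71), Pag1 (-1.68) and Dlx3 (-1.34) lower.

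The beta-actin 5 prime control probe set, which the comparisons did not use, showed a signal of its own. In the -/- lines it was 2.82 higher (log2) with SRF-VP16 than with SRFdM-VP16 (exact p = 0.0286 over 70 splits, the smallest they can give), and without SRF-VP16 it was low, at 6346 ± 4146 on 7 arrays against 19460 ± 3433 on 4 wild-type arrays (-1.94, exact p = 0.0121 over 330 splits). The middle probe set differed by -1.66 (exact p = 0.00909) and the 3 prime one by -0.34 (exact p = 0.127). Without E81 SRFdM-VP16 replicate 1, the array with the lowest Gapdh 5 prime over 3 prime ratio (-0.93), these differences were 2.22 (exact p = 0.0286 over 35 splits, the smallest they can give), -1.58 (exact p = 0.00952 over 210 splits) for the 5 prime, -1.54 for the middle and -0.39 for the 3 prime probe set. Degraded RNA would lower the Gapdh 5 prime over 3 prime ratio too, but that differed by -0.0626 (0.11 without that array), and array scaling would shrink the difference, which was -2.01 after quantile normalization (exact p = 0.00606; -1.73 without that array). The exact tests treat arrays, not lines, as the units, and E14 is the only wild-type line. Genotype and line cannot be told apart here either. On vector and SRFdM-VP16 arrays the 5 prime probe set read 1109 to 5803 in E81, 5323 to 12400 in E100 and 14718 to 22080 in E14. A lower level of beta-actin RNA without SRF-VP16 is a hypothesis that these values do not decide. In the -/- lines the 3 prime probe set was only 0.30 higher with SRF-VP16 (exact p = 0.457). Actb did not pass there, in the main fit or in any of 21 other settings. Why the 5 prime and middle probe sets differ more than the 3 prime one stays unexplained. Actg1, another actin gene with its own probe set, was lower in the same lines. Whether gamma-actin RNA adds to the signal of the beta-actin control probe sets was not tested.

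Genes of the -/- response were high in the wild-type control arrays numbered 2. With vector and SRFdM-VP16 they read 7463 and 7302 for Acta2, 9417 and 11738 for Tagln, and 8843 and 8168 for Krt18, where replicate 1 read -242 and -52, 264 and 591, and 291 and 674. Of the 239 probe sets higher in the -/- lines 58 were more than 1 log2 unit higher in arrays numbered 2, against 719 of the 9404 others. Mislabelled SRF-VP16 arrays would carry every gene that parts the 8 SRF-VP16 arrays from the 13 other control arrays; 5 of 27 such probe sets (18.5%), among them Igfbp6, Nppb and Egr1, lay below all SRF-VP16 arrays in both. Eif2s3y, at 1432 and 1040 in the arrays in question and at most 328 on the 17 arrays of other lines, argues against an array of another line. Igfbp6, at 659 and 1785 on the wild-type SRF-VP16 arrays and 72 and 40 here, argues against an exchange with them. Another wrong label or a mixed sample cannot be told apart from a culture state, because too few genes decide. RNA of fibroblasts would raise the 15 fibroblast genes together, and their median was 0.17 higher, from -1.03 to 1.19; differentiation in these cultures was not tested.

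Probe sets lower with SRFdM-VP16 than with vector came with a shift of the median of all probe sets (-0.20, with 0.01 under quantile normalization and 0.25 after division by the median). Array scaling is a candidate explanation, as is a higher background. On 5 of 8 SRFdM-VP16 arrays 34.0% to 43.6% of values were at or below 0, against 25.2% to 26.95% on the 7 vector arrays. E100 had no such array, but its vector group was not duplicated, so that line cannot decide this. Of the 74 lower calls 0 were left under quantile normalization or division by the median. Their median change went from -1.04 to -0.69 and -0.66 and their median SE from 0.185 to 0.216 and 0.211, so the calls ended through smaller changes and larger spreads, although 72 and 73 of 74 stayed below 0. An effect of the control plasmid on dim transcripts stays open.

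Other splits of the same arrays into groups of the same sizes were fitted to the arrays of each comparison alone with 1 mean per side and no term for line, which adds differences between lines to the spread and gives fewer calls than fits with 1 mean per group. In the -/- lines the real split gave 71 calls and the highest other 87, from the split of E100 against E81, so 2 of 35 splits gave as many and chance was not excluded. With line as a block the real split gave 56 and the highest other 1, but these 18 splits are too few for a share under 0.05. Over all lines the real split gave 32 and the highest other 3, so 1 of 100 drawn from 6435, the real one itself, gave as many. The real split holds equal numbers of arrays of each line per side and the drawn ones need not. Chance is therefore not excluded by these splits. For SRFdM-VP16 against vector the real split gave 3 and the highest other 355, so 6 of 100 gave as many, chance was not excluded, and the arrays hold a structure of their own.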

How the results depend on the processing

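The floors other than the main one, the inverse hyperbolic sine, E100 alone for SRFdM-VP16 against vector, and the omission of wild-type control arrays numbered 2 were tests chosen after the data were seen; the others were planned, and the planned floors at the 10th and 20th percentiles were not run because they are negative. Signal over background limits dim genes: 39.9% of values lie below the floor. Of 3535 values of named genes under other settings 2800 stayed on their side of the threshold, 725 lost their call, 9 gained one and 1 called value reversed: Irf1 over all lines read -0.0881 with vector as the control. Of the 2800, 25 values that passed in neither setting changed sign, for 14 combinations of gene and comparison, among them Acta2 and Tagln in wild type. The cause was not tested for any change below except where named.

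Counts that moved follow as total calls, in short names: null, wt and het are SRF-VP16 against SRFdM-VP16 in -/-, wild-type and E99 cells. Quantile normalization gave wt 7, SRFdM-VP16 against vector 1, -/- against wild type with vector 3, E99 against wild type 3, E81 against E100 3, and an overlap of 1 gene for the calls lower in -/- and higher with SRF-VP16. Division by the median gave wt 7, all lines 342, SRFdM-VP16 against vector 1, -/- against wild type with vector 1, E99 against wild type 2 and E81 against E100 9. No filter gave het 9, SRFdM-VP16 against vector 179, -/- against wild type 87 with vector and 8 with SRFdM-VP16, the -/- against wild-type difference 19 and E81 against E100 22. The filter at the 60th percentile, with fewer probe sets, gave wt 1, het 1, SRFdM-VP16 against vector 0, -/- against wild type 2 and 1, E99 against wild type 0 and E81 against E100 0. No trend gave het 7, -/- against wild type with vector 7, E99 against wild type 8 and E81 against E100 2. A fit of only the arrays of a comparison, with fewer arrays, gave null 112, wt 0, het 0, -/- against wild type 132 and 0, E99 against wild type 0 and the -/- against wild-type difference 3. Vector as the control gave wt 12 and het 10. E81 alone gave null 97; E100 alone gave null 114, SRFdM-VP16 against vector 34 and -/- against wild type 43 and 10. The floor at the 60th percentile gave wt 0, het 0, -/- against wild type 73 and 1, E99 against wild type 6 and the -/- against wild-type difference 18. The inverse hyperbolic sine gave wt 0, het 9, SRFdM-VP16 against vector 120, -/- against wild type 0 and 1, E99 against wild type 0, the -/- against wild-type difference 4 and E81 against E100 1. Without wild-type control arrays numbered 2 the counts were wt 9, SRFdM-VP16 against vector 140, -/- against wild type with vector 50 and E99 against wild type 48. The estimated correlation left 0 of 8 list calls of the -/- comparison.

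The replicate numbers did not pair the arrays in 1 way: over 55 pairs of groups the correlation, across genes, of the difference between replicates 2 and 1 ran from -0.39 to 0.42 (the wild-type vector and SRFdM-VP16 groups), above 0.1 in 29 and below -0.1 in 24. The signs were ordered: 8 groups went together, and 3 (E99 vector, E99 SRFdM-VP16 and wild-type SRF-VP16) went together against them, in all 55 pairs, so the arrays of a group differ along a shared axis that the numbers follow in some groups and oppose in others. No fit removed that axis, because groups of arrays would have to be defined from the measured values; it was seen after the data were examined. A block for the number within lines gave null 245, wt 1, het 0, SRFdM-VP16 against vector 2, -/- against wild type 6 and 2, E99 against wild type 5, the -/- against wild-type difference 4 and E81 against E100 6; a block across lines gave null 266 and all lines 186.

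Leaving out 1 array gave ranges of 194 to 514 for null, 2 to 35 for wt, 4 to 23 for het, 108 to 432 for all lines, 4 to 372 for SRFdM-VP16 against vector, 20 to 61 and 2 to 48 for -/- against wild type, 10 to 50 for E99 against wild type, 4 to 41 for the -/- against wild-type difference and 7 to 430 for E81 against E100. The widest moves came without E81 SRFdM-VP16 replicate 2, which leaves its group with replicate 1 alone, the array with the lowest Gapdh 5 prime over 3 prime ratio (-0.93) and median correlation (0.878): 514 calls for null, 432 for all lines, 372 for SRFdM-VP16 against vector, 48 for -/- against wild type with SRFdM-VP16 and 430 for E81 against E100. At least 155 of the 272 null calls were kept whichever array was left out.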

Other observations

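The tests of gene families below were chosen after the values were seen, so their p-values are no independent support.

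In the -/- lines, SRF-VP16 against SRFdM-VP16, of 23 measured keratins 6 rose (Krt7, Krt8, Krt17, Krt18, Krt19 and Krt20) and Krt81 fell, in the deposited values and under both other scalings (adjusted p = 0.018; 0.11 with an estimated correlation), with a median of 0.25. Krt17 rose by 4.64 and Krt20 by 3.65. The genes that follow here and below outside the counted families were picked from those that passed, so they show no trend of a class. The desmosomal plaque protein Dsp rose by 3.39, from 597 ± 391 to 5170 ± 798, the epithelial cadherin Cdh1 by 1.43 and the epithelial 14-3-3 protein Sfn by 3.96. The trophoblast regulators Gata3 (at least 2.77) and Gata2 (3.11) rose too, Gata3 from the floor to 413 ± 139.

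Of 8 annexins, calcium-dependent membrane-binding proteins, 4 rose (Anxa1 to Anxa4) under all 3 scalings, with a median of 1.69 (adjusted p = 1e-07; 0.013 with an estimated correlation). Of 6 actins 5 rose by the probe set used for each gene, control probe sets left out. All but Actb rose, with a median of 2.81 (adjusted p = 5.7e-12, and 0.0017 with an estimated correlation), and 4 did after division by the array median. The probe sets of Actc1 and Actg2 can cross-hybridise between actins, so these rises may not be separate measurements. Among other cytoskeletal genes the LIM protein Csrp1 rose by 5.46, from 300 ± 264 to 11740 ± 3437, gelsolin (Gsn) by 4.37, a size set in part by the floor, myosin light chain Myl9 by at least 3.67, tropomyosin Tpm4 by 3.24, the actin-disassembly factor Wdr1 by 2.29 and non-muscle myosin Myh9 by 2.06. Of 11 collagen IV and laminin genes 3 rose (Col4a1, Col4a2 and Lama4; adjusted p = 0.24), with 2 rising and Col4a4 falling under both other scalings. Of 9 S100 genes S100a6 rose by 2.88 (adjusted p = 0.24), and none did after division by the median.

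The activin subunit Inhba rose by 4.23, from 88.8 ± 170 to 2434 ± 938, the growth factor Hbegf by 2.06, the phosphatase Dusp2 by 3.78 and the urokinase receptor Plaur by 2.18. Nab2, a co-repressor of Egr factors, rose by 2.13, and the Hippo cofactor Wwtr1 by 1.56; of the YAP and TAZ targets Ccn1 (4.54, set in part by the floor) and Ankrd1 (at least 1.99) rose and Ccn2 did not pass (4.52, adjusted p = 0.067). Caveolar Cavin1 rose by 2.30. Mybl2, a cell-cycle factor, fell by 0.89.

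Eif2s3y read 484 to 1432 on 6 wild-type arrays and -99 to 328 on the 17 others.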
